A study of Mus musculus with 12 samples.

How the data were processed

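RNA was measured in 12 libraries of primary mouse microglia, 3 for each of 4 groups set by brain region and ligand, as the labels give them. Per the labels' protocols, cDNA was made with the SMART-Seq v4 Ultra Low Input kit. Chemistry of this kind primes on the poly(A) tail and does not mark the strand. The extraction protocol in the labels speaks of human tissue, while the organism, the cell type and every other label are mouse, and how the cultured cells were collected is not given in the sources used here. The values deposited by the authors are TPM per Ensembl transcript, not counts. TPM divides the reads of a transcript by its length and scales each library to 1000000, so depth is lost and a rise in some transcripts lowers all others. Per the submitters' processing notes, kallisto 0.43.0 was used with GRCm38. The annotation release, any filter, and any length or GC bias correction are not given in the sources used here. kallisto assigns reads to transcripts without placing them on the genome, so genes with near-identical copies and overlapping antisense genes share reads in ways that these values cannot resolve.

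The table held 115879 transcripts of 46262 genes. TPM was summed per gene with the gene identifiers of the table. For location, length and GC content, transcripts were matched to the GENCODE M21 annotation of GRCm38, in which 114255 (98.6%) were found. No pair among the 66 pairs of libraries held identical values. The low values of a TPM table do not reveal depth, since each value is divided by its transcript's effective length, and so no counting interval or floor is given, and precision rests on the spread between libraries.

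The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 4 group means, a shared variance with trend, 8 residual degrees of freedom and Benjamini-Hochberg adjustment over the 12419 genes with at least 1 TPM in at least 3 of the 12 libraries, called at an adjusted p under 0.05. All tests were two-sided. Log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The 6 contrasts were IL-34 against CSF-1 in forebrain, in cerebellum and as the mean of both regions, the region by ligand interaction, and cerebellum against forebrain under each ligand. All adjusted p-values of genes are from limma. Gene lists were tested with camera, also in limma, which asks whether a list's genes lie higher or lower than the other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation. Of 41 lists written in advance, with 1019 entries in all, 35 had at least 5 genes measured. The preset value called 16, 15, 17, 2, 17 and 15 lists in the 6 contrasts in the order above, and the estimated correlation kept 3, 1, 1, 0, 3 and 2 in turn. With the preset value, most other splits of the libraries called some lists as well. The lists overlap, and their choice rests on general knowledge of microglia.

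The groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule takes for each contrast the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 5 TPM in the higher group, a symbol that is not that of a predicted gene or pseudogene, and no overlap between the libraries compared (for the mean of both regions, in neither region; for the interaction, without this last condition). It also takes up to 4 members with the smallest p of each list described, and Csf1r, Csf1, Il34, Ptprz1, Sdc1 and Trem2 in all groups. Rpl10-ps3 was not caught by the pattern for pseudogene symbols and is named as uncertain. Some genes that the rule takes are not reported here.

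Alternatives covered the pseudocount, the filter on low values, scaling between libraries, the variance model, library weights, the replicate number as a block, the libraries in the fit and leaving out each library in turn. Chosen after seeing the data were the sum over transcripts of 1000 nt or more (11486 genes kept), the same with each library's smooth trends of length and GC content removed (lowess, span 0.3), the length floor of each library as a covariate, and a fit on 9 libraries without the 3 with the highest length floor. For the gene lists, quantile normalization and the scaling without mitochondrial and ribosomal genes were also chosen then, and so was leaving out each library for the lists and for the correlation of ligand effects. Other splits of the libraries were counted for each contrast, and for the interaction again with each gene's mean ligand difference of both regions subtracted, without the split that this fixes at 0. In simulations, all 12 libraries were drawn independently around each gene's forebrain CSF-1 mean, with its fitted spread. When 200 of 12419 genes were changed in the forebrain IL-34 group, limma recovered 53.7, 88.1 and 95.5% of those changed by 0.5, 1 and 2 on the log2 scale. Of these calls 3.07% were false. With the changes in the cerebellar IL-34 group it recovered 49.3, 94.0 and 93.9%, with 3.66% false. These simulations held no length floor and no libraries that deviate together, so their false shares need not hold for the real data. In a further one with a length trend added to the cerebellar IL-34 group, trend removal lowered the calls from 3454 to 195. It recovered 186 of the 200 changed genes, against 191 before. Values were prepared with Python 3.11.15 and pandas 2.3.3.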

Results

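The series profiled RNA from primary mouse microglia, the resident macrophages of the brain, grown out of mixed glial cultures of forebrain or cerebellum and then kept for 24 hours with recombinant CSF-1 at 20 ng/ml or IL-34 at 100 ng/ml. Both cytokines bind the receptor encoded by Csf1r, which microglia need for survival. The labels give 4 groups of 3 libraries, forebrain with CSF-1, forebrain with IL-34, cerebellum with CSF-1 and cerebellum with IL-34, and the design text describes the cultures as independent. There was no group without a ligand, and the ligands were used at different doses. The deposited values are TPM, a length-corrected share of each library's transcripts, and every library sums to 1000000, so the number of reads behind a value is unknown. Between 11740 and 11904 genes per library had at least 1 TPM. Across genes, Pearson's r between libraries of the same group lay between 0.972 and 0.99 over 12 pairs, and between libraries of different groups between 0.946 and 0.988 over 54 pairs. Genes are not independent replicates, and these values describe the libraries only.

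Short transcripts were measured unevenly. Transcripts under 600 nt held 2.58, 3.31 and 0.947% of TPM in the cerebellar libraries with IL-34, and between 0.0269 and 0.555% in each of the 9 others. Of 246 protein-coding genes whose longest transcript was under 400 nt, 0 had a value above 0 in any library. The length floor of a library, taken as the length below which 1 percent of its transcripts at 5 TPM or more fell, was 503, 491 and 580 nt in the cerebellar IL-34 libraries and 592 nt or more in the rest. The first principal component, the axis of largest variation between libraries, held 41.1% of the variance and had r = -0.97 with this floor. Longer transcripts were affected too. For IL-34 against CSF-1 in cerebellum, the median log2 fold change was 0.415 for genes under 800 nt and -0.155 at 3000 nt or more. Atox1, a copper chaperone, Cox8a, a subunit of cytochrome c oxidase, and the metallothionein Mt1 were listed at 0 in those 9 libraries, so a value of 0 for a short gene is not read here as absence.

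**Figure D1:**
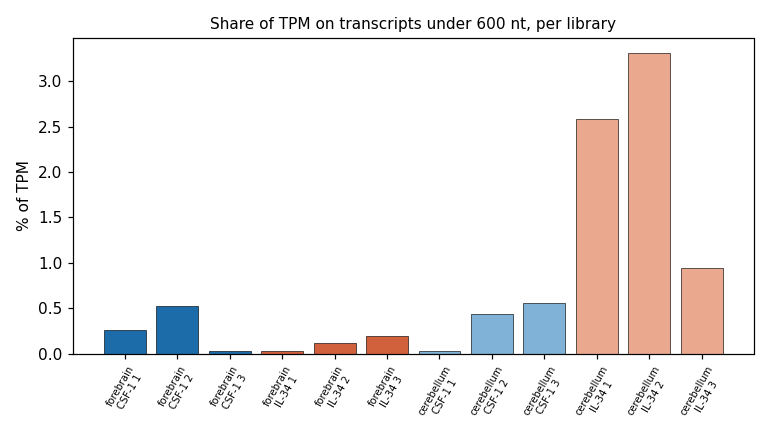
Share of TPM on transcripts under 600 nt (percent, y axis) in each of the 12 libraries (x axis, named by region, ligand and replicate; 1 bar per library). The 3 cerebellar IL-34 libraries sit at 0.947% or above and the 9 others at 0.555% or below.

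The receptor gene and its partners came first. Csf1r was among the abundant transcripts, at 1200 ± 65.3 TPM in forebrain with CSF-1, 1240 ± 78.6 in forebrain with IL-34, 1300 ± 44.4 in cerebellum with CSF-1 and 1190 ± 36.5 in cerebellum with IL-34 (mean ± SD, n = 3 in each group, as throughout). Trem2, a lipid-sensing receptor of microglia, lay between 799 ± 20.6 and 888 ± 39.9 TPM. Csf1 lay between 9.57 ± 0.463 and 12.1 ± 3.52 TPM in the cerebellar groups and at 12.1 ± 0.765 and 13 ± 1.8 TPM in the forebrain groups. None of these 3 genes passed in any of the 6 contrasts tested. Sdc1, which encodes the cell surface proteoglycan syndecan-1, passed only for the mean ligand difference of both regions, where it was higher with IL-34 (log2 fold change 0.30, adjusted p = 0.0333). Ptprz1, another reported receptor of IL-34, had 0.910 ± 0.0853 and 0.714 ± 0.198 TPM in the forebrain groups and 0.196 ± 0.0525 and 0.200 ± 0.0522 TPM in the cerebellar groups, below the level needed for testing. Il34 was at most 0.222 TPM in any library and was listed at 0 in 7 of them.

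The ligand comparison asks how microglia kept in IL-34 differ from those kept in CSF-1, first as the mean of both regions. With IL-34, Ccnd1, Ccl2 and Ch25h were lower, and Atp6v0d2 and Hgf were higher. Ccnd1, the gene of cyclin D1 that carries cells through G1 (ENSMUSG00000070348, GRCm38 chromosome 7, 144929931 to 144939925, minus strand), fell from 45.1 ± 6.69 to 23.2 ± 1.34 TPM in forebrain and from 49.8 ± 0.907 to 21.3 ± 4.64 TPM in cerebellum. The chemokine gene Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453, plus strand) fell from 79.2 ± 7.26 to 39.0 ± 4.52 and from 32.3 ± 2.84 to 17.8 ± 1.71 TPM. Ch25h, the gene of cholesterol 25-hydroxylase (ENSMUSG00000050370, chromosome 19, 34473778 to 34475164, minus strand), fell from 233 ± 27.8 to 133 ± 2.61 and from 118 ± 3.43 to 58.1 ± 6.41 TPM. Atp6v0d2, a subunit of the proton pump that acidifies lysosomes (ENSMUSG00000028238, chromosome 4, 19876841 to 19922605, minus strand), rose from 18.4 ± 0.749 to 32.7 ± 2.98 and from 25.0 ± 1.89 to 39.8 ± 5.97 TPM.

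Of 12419 genes tested with limma, 1667 passed for this mean difference, 339 higher and 1328 lower with IL-34, and 3697 had an unadjusted p under 0.05. The share of higher calls was 20.3%, and it depended on scaling: median-of-ratios scaling gave 712 higher and 615 lower genes (53.7% higher) and quantile normalization 474 higher and 735 lower (39.2%). It also went with transcript length: 67 genes were higher and 631 lower at 3000 nt or more, and 39 higher and 10 lower under 800 nt. With transcripts of 1000 nt or more and trends removed, 1030 were higher and 1025 lower. Trend removal also recentres each library, so this balance need not come from length. By the naming rule the highest genes included the fatty acid binding proteins Fabp4 (log2 fold change 0.99, SE 0.13) and Fabp5 (0.73, SE 0.09), the tetraspan gene Ms4a4c (0.87), Ypel3 (0.68), the immediate early gene Egr1 (0.64), the growth factor gene Hgf (0.63), Pianp (0.62) and Tmem203 (0.61). Cox16, an assembly factor of cytochrome c oxidase, was also among them (0.67, adjusted p = 0.0058), but with transcripts of 1000 nt or more alone its difference was -0.98, and it did not pass. When the length and GC trends of these longer transcripts were removed as well, Fabp5 was at 0.38 (adjusted p = 0.0587) and Ms4a4c at 0.28 (adjusted p = 0.118), so both lost the call, and Fabp4 was at 0.53 (adjusted p = 0.00104). The lowest included Ccnd1 (-1.07, adjusted p = 0.000197), Ccl2 (-0.91, adjusted p = 7.72e-05), Ch25h (-0.91, adjusted p = 3.67e-05), Plau (-0.89), which encodes urokinase, the organic anion transporter gene Slco2b1 (-0.88), Rrm2 (-0.85), a subunit of the enzyme that makes deoxyribonucleotides, the chemokine gene Ccl7 (-0.80), the basement membrane gene Nid2 (-0.80) and the AP-1 gene Fosl1 (-0.79). The count was 1034 without cerebellum IL-34 replicate 2, 1088 and 1046 without forebrain CSF-1 replicates 2 and 3, and 925 and 990 without forebrain IL-34 replicates 2 and 3. With the length floor of each library as a covariate, 622 genes passed. Tmem203, with a mean transcript length of 854 nt, was not among them (limma adjusted p = 0.0971), and it was not measured with longer transcripts. Slco2b1 and Rrm2 were at -0.54 and -0.49 after trend removal and still passed.

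The lists of related genes gave the following counts. Of 41 genes of the G1/S list, 19 fell with IL-34, 0 rose and 22 did not pass, and 25 were lower when adjusted over the list alone. Mcm5 (-0.66), Uhrf1 (-0.64), Mcm6 (-0.34) and Rrm2 had its smallest p (camera adjusted p = 1.92e-07, and adjusted p = 0.0783 with an estimated correlation). Of 50 genes of the G2/M list 14 fell, 20 when adjusted over the list alone, among them Gtse1 (-0.76) and Tubb4b (-0.42) (adjusted p = 0.000252, and adjusted p = 0.0656 with an estimated correlation). Targets of the ERK pathway fell in 12 of 19 cases and rose in 1, 13 and 1 when adjusted over the list alone, led by the phosphatase gene Dusp5 (-0.54), Ccnd1, the urokinase receptor gene Plaur (-0.50) and the ERK inhibitor Spred1 (-0.45) (adjusted p = 4.38e-05, and adjusted p = 0.0656 with an estimated correlation). Of 23 glycolysis genes 11 fell, 15 when adjusted over the list alone, including Pdk1 (-0.57), Pkm (-0.26) and Eno1 (-0.17) (adjusted p = 0.0002, and adjusted p = 0.288 with an estimated correlation). Chaperone genes of the unfolded protein response fell in 10 of 19 cases, 13 lower and 1 higher when adjusted over the list alone, led by Hyou1 (-0.41), Calr (-0.25), Hspa5 (-0.21) and Pdia4 (-0.17) (adjusted p = 0.00774, and adjusted p = 0.311 with an estimated correlation). Genes of the heat shock and dissociation stress list, which was set as a sign of sample quality, moved with these groups: 8 of 14 fell, 10 when adjusted over the list alone, led by Hspa8 (-0.26), Chordc1 (-0.26) and Hsp90ab1 (-0.30) (adjusted p = 0.00247, and adjusted p = 0.288 with an estimated correlation). The chemokine list, which holds Ccl2 and Ccl7, had 4 of 17 genes lower and 1 higher, 4 and 2 when adjusted over the list alone, with a median log2 fold change of 0.11, and it did not pass (adjusted p = 0.363). Some of these counts depended on scaling: median-of-ratios scaling gave 6 G2/M genes lower and 1 higher, 7 glycolysis genes lower and 1 higher, 4 chaperone genes lower and 1 higher, 5 heat shock genes lower and 2 chemokine genes lower. Quantile normalization gave 6 G2/M genes and 5 chaperone genes lower. Pdk1 (-0.35), Pkm (-0.17), Eno1 (-0.09), Hspa5 (-0.12), Pdia4 (-0.09), Chordc1 (-0.14) and Hsp90ab1 (-0.12) were smaller after trend removal among longer transcripts and still passed.

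Of 51 lysosomal genes 13 rose and 1 fell, 19 and 3 when adjusted over the list alone, led by the cathepsin genes Ctss (0.27), Ctsh (0.27), Ctsl (0.30) and Ctsz (0.16) (adjusted p = 2.24e-11, and adjusted p = 0.0743 with an estimated correlation). The list of genes raised in disease-associated microglia had 12 of 34 higher and 3 lower, 18 and 3 when adjusted over the list alone, and kept its call with an estimated correlation (adjusted p = 2.36e-11 with the preset value and 0.0119 with the estimate). Gpnmb (0.37), Atp6v0d2 and Fabp5 rose within it, the latter without a call after trend removal, while Ch25h fell. Of 41 type I interferon response genes 8 rose, 10 when adjusted over the list alone, including Ifit2 (0.33), Ifit3 (0.23), Zbp1 (0.29) and Usp18 (0.13) (adjusted p = 2.93e-08, and adjusted p = 0.18 with an estimated correlation). Cholesterol biosynthesis genes rose in 5 of 31 cases, 9 when adjusted over the list alone, among them Mvd (0.29), Hmgcs1 (0.22) and Fdft1 (0.22) (adjusted p = 1.92e-07, and adjusted p = 0.0849 with an estimated correlation). Among 12 genes of growth factor receptors and CSF1R ligands, 4 rose, the same number when adjusted over the list alone: Csf3r, the receptor gene for G-CSF (0.55), Csf2rb (0.31), Csf2rb2 (0.24) and Sdc1 (adjusted p = 0.00237, and adjusted p = 0.129 with an estimated correlation). Of 10 mitochondrially encoded genes, another sign of sample quality, 1 rose, the same number when adjusted over the list alone (adjusted p = 0.00571, and adjusted p = 0.288 with an estimated correlation), and with trends removed among the 5 measured with longer transcripts the list did not pass (adjusted p = 0.412). Inflammatory genes were mixed, with 7 of 29 higher and 3 lower, 8 and 5 when adjusted over the list alone. Ptgs2, the gene of the inducible prostaglandin synthase (-0.57), Nlrp3, an inflammasome sensor (-0.51), and Marcksl1 (-0.34) fell and Cd83 (0.46) rose (adjusted p = 0.00924, and adjusted p = 0.537 with an estimated correlation). Median-of-ratios scaling gave 29 lysosomal genes higher and 0 lower, 12 cholesterol biosynthesis genes higher, and 18 genes of the disease-associated list higher and 1 lower. Quantile normalization gave 14 lysosomal genes higher and 0 lower and 8 cholesterol biosynthesis genes higher. After trend removal among longer transcripts Zbp1 (0.18) and Csf2rb2 (0.37) still passed.

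**Figure D2:**
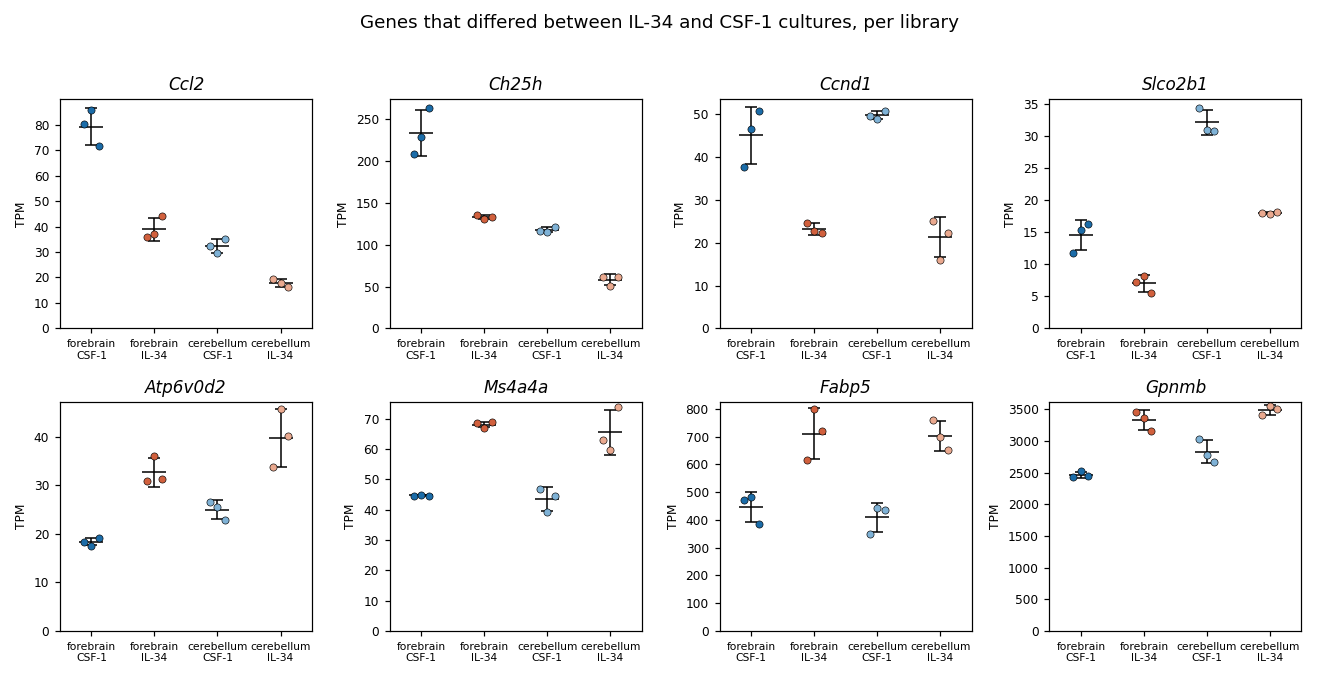
TPM of 8 genes (1 panel each, linear y axis from 0) in the 4 groups; points are libraries, the horizontal mark is the group mean and the bar is ± 1 SD (n = 3). Ccl2, Ch25h, Ccnd1 and Slco2b1 are lower and Atp6v0d2, Ms4a4a, Fabp5 and Gpnmb higher with IL-34 in both regions, with no overlap between the ligands' libraries within a region.

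In forebrain alone, IL-34 cultures had about 2-fold less Ccl7 and Ccl2 transcript and more Hgf, Atp6v0d2 and Fabp5. Ccl7 (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525, plus strand) fell from 37.4 ± 3.00 to 17.9 ± 3.57 TPM, and Ccl2 lies beside it. With transcripts of 1000 nt or more and trends removed Ccl2 was at -0.85 and did not pass (adjusted p = 0.0769), and Ccl7 was not measured. Slco2b1 fell from 14.5 ± 2.35 to 7.03 ± 1.35 TPM (log2 fold change -0.95, SE 0.13) and Plau from 13.4 ± 0.701 to 7.41 ± 0.337 TPM (-0.77, SE 0.11). Hgf, the hepatocyte growth factor gene (ENSMUSG00000028864, chromosome 5, 16553495 to 16620152, plus strand), rose from 4.78 ± 0.702 to 9.21 ± 1.39 TPM (0.82, SE 0.14), and Fabp5 rose from 447 ± 53.7 to 711 ± 91.8 TPM (0.67, SE 0.12). In this contrast 149 genes passed, 53 higher and 96 lower with IL-34 (35.6% higher), and 1769 had an unadjusted p under 0.05. All 149 separated the 3 and 3 libraries without overlap. Chance gives this to 10% of genes, but these were picked by a test on the same libraries, so it is no added support. Of the 149, 3 differed more than 2-fold. Median-of-ratios scaling gave 253 genes, 139 higher and 114 lower (54.9% higher), and quantile normalization 165, 87 higher and 78 lower (52.7%).

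Other named genes that rose in forebrain were Cav1, the gene of caveolin-1 (0.64), Egr1 (0.64), Mgst1, a microsomal glutathione transferase (0.63), Mxd4, a MYC antagonist (0.61), Ccrl2, a non-signalling chemerin receptor (0.60), Fam46c (0.60) and Ms4a4a (0.59). Rrm2 (-0.96), Ccnd1 (-0.92), Gtse1 (-0.82), Ch25h (-0.80), Nid2 (-0.78) and Uhrf1 (-0.77), which maintains DNA methylation through replication, fell. With trends removed among longer transcripts Mgst1 (0.40) and Rrm2 (-0.59) still passed, and Ms4a4a was not measured. Of 41 G1/S genes 4 fell, 18 when adjusted over the list alone (adjusted p = 2.89e-09, and adjusted p = 0.0581 with an estimated correlation). In the ERK target list 4 of 19 fell and 1 rose, 11 and 1 when adjusted over the list alone, with Plaur at -0.67, Dusp5 at -0.46 and Phlda1 at -0.62 (adjusted p = 1.07e-06, and 0.0385 with an estimated correlation). The list of disease-associated microglia had 6 of 34 genes higher and 1 lower, 9 and 1 when adjusted over the list alone (adjusted p = 2.18e-08, and 0.038 with an estimated correlation). Of 51 lysosome genes Ctss (0.30), Ctsl (0.42) and Ctsh (0.27) rose, and 10 were higher when adjusted over the list alone (adjusted p = 2.82e-11, and adjusted p = 0.0694 with an estimated correlation). Median-of-ratios scaling gave 11 of 51 higher and quantile normalization 6. Csf3r (0.46) and Csf2rb (0.35) rose among 12 growth factor receptor and ligand genes, 4 when adjusted over the list alone (adjusted p = 0.00039, and adjusted p = 0.0758 with an estimated correlation). Leaving out forebrain IL-34 replicate 2 gave 29 genes, forebrain IL-34 replicate 3 gave 70, forebrain CSF-1 replicates 2 and 3 gave 58 and 62, and cerebellum CSF-1 replicate 2 gave 92. In the heat shock and dissociation stress list 1 of 14 genes was lower, 2 when adjusted over the list alone (adjusted p = 0.00239, and adjusted p = 0.297 with an estimated correlation). Of the 12 fits that each left out 1 library, Egr1 passed in 3, Mxd4 in 4, Cav1, Fabp5 and Rrm2 in 7, Hgf, Mgst1 and Ccnd1 in 8, Ccrl2 in 9 and Ccl7 in 10. Gtse1, Uhrf1 and Plau lost the call only without forebrain IL-34 replicate 2. With only the 6 forebrain libraries in the limma fit 0 genes passed and 1646 had an unadjusted p under 0.05.

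In cerebellum, the genes with the largest decrease under IL-34 that were measured with long transcripts included Ccnd1 (log2 fold change -1.21, SE 0.14), Dmpk, the myotonic dystrophy kinase gene (-1.37, SE 0.21), which fell from 11.2 ± 3.21 to 3.62 ± 0.603 TPM, and the helicase gene Dhx9 (-1.04, SE 0.18), which fell from 8.80 ± 1.68 to 3.79 ± 1.07 TPM. Ramp2, a receptor-modifying protein gene, was lower (-1.61, adjusted p = 0.0146), but did not pass without cerebellum CSF-1 replicate 1 or IL-34 replicate 2. Pagr1a had 17.6, 19.4 and 24.6 TPM with CSF-1 and 4.58e-08, 0.000222 and 3.67 TPM with IL-34 (-3.67). Values such as 4.58e-08 TPM may reflect how shared reads were assigned, so Pagr1a is uncertain and is not read as near absence. Cdk5rap2 was lower by the same test (-1.25), but with transcripts of 1000 nt or more and the length and GC trends removed its difference was -0.01 (adjusted p = 0.964). Junos (-2.83), which lies antisense to Jun, and Zfp600 (-2.73), which has near-identical copies, are uncertain. All 10 of the highest named genes had mean transcript lengths of 768 nt or less. Atox1, Cox8a, Mt1, mt-Nd6, Wfdc17, Tceb2 and Cd52 were listed at 0 in the 3 cerebellar CSF-1 libraries, Mif and Uqcrb were above 0 in 1 of them, and the pseudogene Rpl10-ps3, whose value is uncertain, was at 6.52e-06 TPM or less.

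In this contrast 1593 genes passed, 373 higher and 1220 lower with IL-34 (23.4% higher), and 3843 had an unadjusted p under 0.05. Median-of-ratios scaling moved the median of all genes from -0.10 to 0.003 and gave 710 higher and 483 lower genes (59.5% higher), and quantile normalization gave 451 higher and 724 lower (38.4%). Calls went with transcript length: 50 genes were higher and 596 lower at 3000 nt or more, and 70 higher and 13 lower under 800 nt. With transcripts of 1000 nt or more and trends removed, 747 were higher and 779 lower. This setting also recentres each library, so the balance need not come from length. Of the 1451 main calls measured there, 703 still passed in the same direction. Of the list of disease-associated microglia, 11 of 34 genes rose and 2 fell, 15 and 3 when adjusted over the list alone (adjusted p = 2.68e-08, and 0.03 with an estimated correlation), with Fabp5 at 0.79, Atp6v0d2 at 0.64 and Ch25h at -1.01, beside the short gene Cd52. With transcripts of 1000 nt or more and trends removed Fabp5 was at -0.12 and did not pass (adjusted p = 0.714). Of 41 G1/S genes 15 fell, 22 lower and 1 higher when adjusted over the list alone, led by Mcm5 (-0.72), Mcm2 (-0.64), Mcm6 (-0.39) and Mcm4 (-0.42) (adjusted p = 0.000552, and adjusted p = 0.315 with an estimated correlation). Median-of-ratios scaling gave 8 lower and 1 higher and quantile normalization 9 lower. In the ERK target list 9 of 19 fell and 1 rose, and the same numbers when adjusted over the list alone, led by Dusp5 (-0.62), Ccnd1, Spred1 (-0.55) and Etv5 (-0.40) (adjusted p = 0.00281, and adjusted p = 0.233 with an estimated correlation). Of 23 glycolysis genes 9 fell, 18 when adjusted over the list alone, with Pdk1 at -0.77, Pkm at -0.29, Pgk1 at -0.60 and Eno1 at -0.18 (adjusted p = 0.000217, and adjusted p = 0.353 with an estimated correlation). With those scalings 4 and 5 were lower. Trend removal among longer transcripts left Mcm2 at -0.32, Mcm4 at -0.26, Spred1 at -0.32, Etv5 at -0.25, Pdk1 at -0.39, Pkm at -0.18, Pgk1 at -0.36 and Eno1 at -0.09, all still past the threshold. In the heat shock and dissociation stress list 7 of 14 fell, 8 when adjusted over the list alone (adjusted p = 0.0287, and adjusted p = 0.541 with an estimated correlation). Of these 14 genes, 4 were lower with median-of-ratios scaling and 5 with quantile normalization. Of 52 nuclear genes for respiratory chain subunits 10 were higher and 2 lower, 16 and 5 when adjusted over the list alone (adjusted p = 9.94e-08, and adjusted p = 0.256 with an estimated correlation), and with trends removed among transcripts of 1000 nt or more the list pointed down and did not pass (adjusted p = 0.333). With the length floor as a covariate, a measure that sets the cerebellar IL-34 libraries apart from the rest, 37 genes passed. Ccnd1, Dmpk, Dhx9 and Pagr1a were not among them (limma adjusted p = 0.0905, 0.0928, 0.27 and 0.139). The count was 434 and 680 without cerebellum CSF-1 replicates 1 and 2, and 825 and 299 without cerebellum IL-34 replicates 1 and 2.

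Genes called for the ligand in forebrain mostly moved the same way in cerebellum. Of the 149 forebrain calls, 148 had the same sign there, 38 were called higher in both regions and 80 lower in both, against 1.59 and 9.43 expected from independent lists, and 0 were called in opposite directions by limma. The regions' contrasts share no libraries, but both use each gene's spread over all 12 libraries. Genes with a small spread are favoured in both lists, so the expected counts may be too low. Over these 149 genes the cerebellar log2 fold change had a slope of 0.809 on that of forebrain (Pearson's r = 0.915, across genes chosen by their forebrain test). Over all 12419 genes Pearson's r was -0.0225 and Spearman's rho 0.224, both across genes, which are not independent replicates. With transcripts of 1000 nt or more and the trends removed, r was 0.205, and 835 of 880 forebrain calls had the same sign in cerebellum. Of these, 271 were called higher in both regions and 222 lower in both, against 29.8 and 28.6 expected from independent lists, and 2 genes were called in opposite directions.

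**Figure D3:**
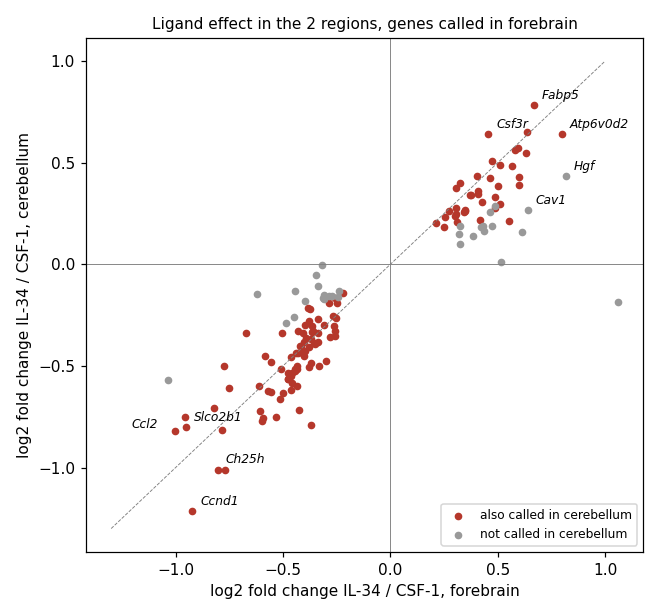
Log2 fold change of IL-34 against CSF-1 in forebrain (x axis) and cerebellum (y axis) for the 149 genes called in forebrain (1 point per gene; red, also called in cerebellum; grey, not called there; dashed line, equal change). Of the 149 points, 148 lie in the quadrants of equal sign.

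The test of the region by ligand interaction asks whether the ligand difference itself differed between regions. It passed for 18 genes, 15 with a more positive difference in cerebellum and 3 with a more negative one, and 1505 genes had an unadjusted p under 0.05. Of the 18 genes, 12 were listed at 0 in the 9 libraries other than cerebellum with IL-34. In the latter, replicates 1, 2 and 3 had 275, 248 and 162 TPM of Atox1, 154, 154 and 51.7 of Cox8a, 150, 150 and 50.1 of Mt1, 121, 151 and 29.5 of Wfdc17, a secreted protein gene of the whey acidic protein family, 69.6, 69.7 and 22.5 of Tceb2, which encodes elongin B, and 5.57, 5.90 and 5.69 of Mt2. Atox1 is on chromosome 11 (55446641 to 55461239, minus strand). The others named by the rule had longer transcripts: Mrps5, a mitochondrial ribosomal protein gene (1.44, adjusted p = 0.0345), Focad (1.39, adjusted p = 0.0186), Plekhm2 (0.81, adjusted p = 0.0393) and Nup98, a nuclear pore gene (-0.58, adjusted p = 0.025). With transcripts of 1000 nt or more Mrps5 was at -0.02 and Focad at -0.05. With the length and GC trends removed as well, limma called 0 genes, and 1377 had an unadjusted p under 0.05. Of the 12 fits that each left out 1 library, Mrps5 and Plekhm2 passed in 2, Nup98 in 3 and Focad in 7. The count was 29 without cerebellum CSF-1 replicate 3 and 132 without cerebellum IL-34 replicate 3. Among lists, nuclear respiratory chain genes had 1 of 52 higher, 6 higher and 1 lower when adjusted over the list alone (adjusted p = 3.91e-08, and adjusted p = 0.967 with an estimated correlation), and ribosomal proteins 0 of 53, with 3 higher when adjusted over the list alone (adjusted p = 8.42e-06, and adjusted p = 0.967 with an estimated correlation). With transcripts of 1000 nt or more both lists pointed down and did not pass (adjusted p = 0.984 and 0.078). After trend removal as well, the ribosomal list was called lower (adjusted p = 0.00282) and the respiratory chain list did not pass (adjusted p = 0.77).

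The regional comparison asks how cerebellar and forebrain microglia differ under the same ligand. Under CSF-1, cerebellar cultures had more transcript of the potassium channel gene Kcnn4, the cystine transporter gene Slc7a11 and the microglial surface gene Tmem119. They had less of several genes typical of macrophages at the brain's borders, and less of the complement genes Cfp and C2. Kcnn4 (ENSMUSG00000054342, chromosome 7, 24370263 to 24386690, plus strand) had 20.4 ± 0.402 TPM in forebrain and 80.9 ± 5.30 in cerebellum (log2 fold change 1.94, SE 0.07). Slc7a11 had 13.4 ± 0.679 and 34.7 ± 1.29 TPM (1.31, SE 0.07), and Tmem119 8.88 ± 1.51 and 18.8 ± 1.39 TPM (1.01, SE 0.11). Folr2, the gene of folate receptor beta (ENSMUSG00000032725, chromosome 7, 101839988 to 101857194, minus strand), had 90.9 ± 4.31 TPM in forebrain and 25.5 ± 0.685 in cerebellum (-1.79, SE 0.07). F13a1, the gene of the coagulation factor XIII A chain (ENSMUSG00000039109, chromosome 13, 36867178 to 37050244, minus strand), had 28.7 ± 1.39 and 6.19 ± 0.530 TPM (-2.05, SE 0.10), and Vsig4, a complement receptor gene, had 7.37 ± 2.09 and 0.218 ± 0.0714 TPM (-2.75, SE 0.20).

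In this contrast 833 genes passed, 408 higher and 425 lower in cerebellum, and 2839 had an unadjusted p under 0.05. All 833 were without overlap between libraries, which their selection by a test on the same libraries nearly fixes. Other high genes named by the rule were Enpp2, the gene of autotaxin (3.06), the protease inhibitor gene Spint1 (1.88), the sorting receptor gene Sorl1 (1.38), Dkk2, a Wnt modulator (1.28), Slco2b1 (1.11), the matrix gene Emilin1 (1.11, and 0.70 after trend removal among longer transcripts) and Tmem176a (1.09). Ttr, which encodes transthyretin and is made in quantity by the choroid plexus, had 18.4 ± 5.75 TPM in cerebellum, and 0.257 TPM in 1 forebrain library and a listed 0 in the other two. Enpp2 followed Ttr across the cerebellar libraries. With CSF-1 Enpp2 had 10.8, 6.73 and 12.6 TPM against 17.1, 13.4 and 24.7 of Ttr. With IL-34 it had 10.6, 5.11 and 19 against 21, 8.95 and 38. Whether either transcript came from microglia or other cells was not tested. Lower genes included Fcna, a ficolin gene (-2.20), Igfbp3 (-2.11), the cyclophilin gene Ppic (-1.98), Vill (-1.79), the cathepsin gene Ctsk (-1.74), Cav1 (-1.58) and the inhibitory receptor gene Pilra (-1.55). The count was 502 and 413 without cerebellum CSF-1 replicates 1 and 2, and 441 and 535 without forebrain CSF-1 replicates 1 and 3. It was 1805 with transcripts of 1000 nt or more and trends removed, and 456 with only the 6 libraries compared.

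Under CSF-1 the lists gave the following counts between regions. Of 50 G2/M genes 14 were lower in cerebellum and 1 higher, 23 and 1 when adjusted over the list alone, with Ccnb2, a cyclin gene, in front, and with Top2a at -0.89, Gtse1 at -0.61 and Hmmr at -0.68 (adjusted p = 7.54e-11, and 0.00554 with an estimated correlation). Of 41 type I interferon response genes 8 were lower, 14 when adjusted over the list alone, led by Slfn2 (-0.36), Usp18 (-0.33), Ifit3 (-0.43) and Ifit2 (-0.59) (adjusted p = 2.06e-09, and adjusted p = 0.169 with an estimated correlation). With median-of-ratios scaling 13 were lower. Border-associated macrophage genes were lower in 6 of 11 cases, 7 lower and 1 higher when adjusted over the list alone: Folr2, F13a1, Cd38 (-1.15) and Clec12a (-0.44) had the smallest p (adjusted p = 9.81e-07, and 0.0065 with an estimated correlation). Complement genes were lower in 3 of 16 cases, 6 lower and 1 higher when adjusted over the list alone, namely Cfp, the properdin gene (-0.99), C2 (-1.26) and C1qb (-0.17) (adjusted p = 0.000432, and adjusted p = 0.0753 with an estimated correlation). Of 17 chemokine genes 5 were lower, 6 when adjusted over the list alone, including Ccl2 (-1.27), Ccl7 (-1.42), Ccl4 (-0.78) and Cxcl16 (-0.18) (adjusted p = 0.00475, and adjusted p = 0.334 with an estimated correlation), and the list did not pass with trends removed among transcripts of 1000 nt or more (adjusted p = 0.444). Cholesterol biosynthesis genes were higher in 12 of 31 cases, 14 when adjusted over the list alone, among them the desaturase gene Scd2 (0.92), Sc5d (0.42) and Fads1 (0.35) (adjusted p = 2.06e-08, and adjusted p = 0.0789 with an estimated correlation). Of 20 genes of the NRF2 antioxidant response 8 were higher, 10 when adjusted over the list alone, with Slc7a11, Gclm (0.35), Cat (0.32) and Srxn1 (0.36) in front (adjusted p = 3.81e-05, and adjusted p = 0.136 with an estimated correlation). Homeostatic microglia genes were higher in 4 of 29 cases, 8 when adjusted over the list alone: Tmem119, Slco2b1, Entpd1 (0.66) and Mef2c (0.51) (adjusted p = 0.00162, and adjusted p = 0.38 with an estimated correlation). With quantile normalization 7 were higher.

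**Figure D4:**
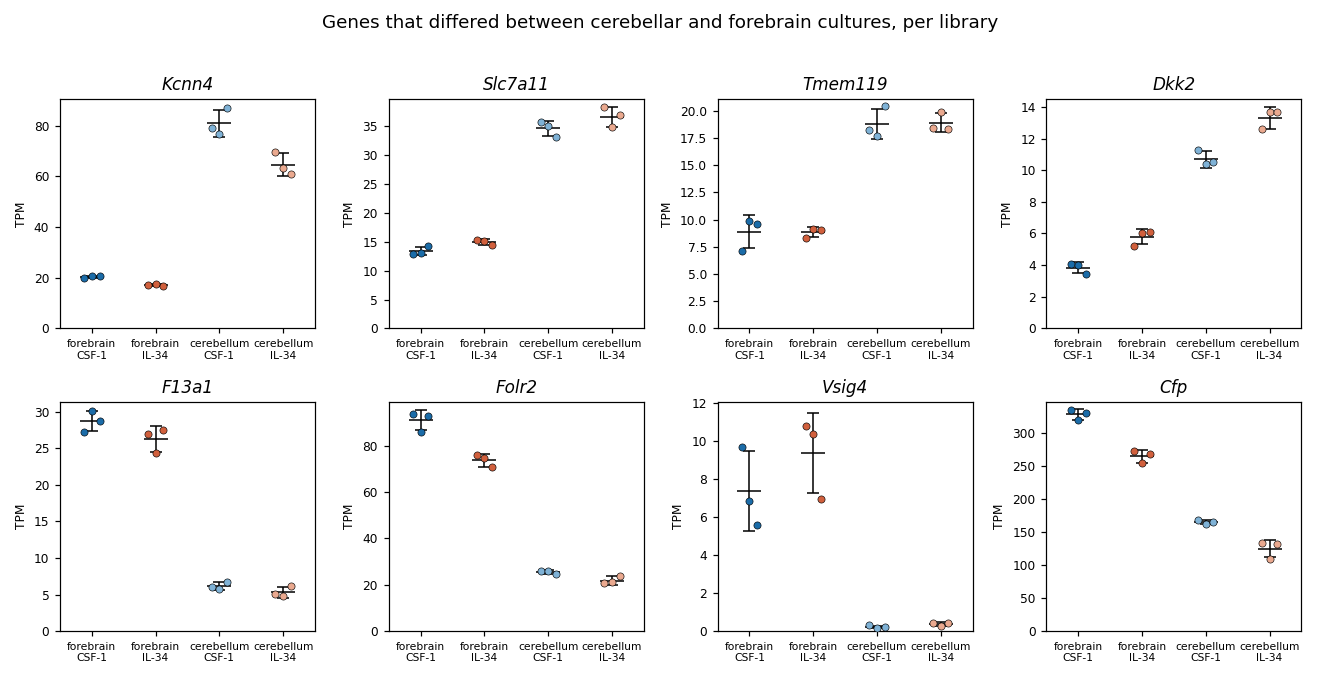
TPM of 8 genes (1 panel each, linear y axis from 0) in the 4 groups; points are libraries, the horizontal mark is the group mean and the bar is ± 1 SD (n = 3). Kcnn4, Slc7a11, Tmem119 and Dkk2 are higher and F13a1, Folr2, Vsig4 and Cfp lower in cerebellum than in forebrain under both ligands, with no overlap between the regions' libraries.

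Under IL-34 many of these genes separated the regions as well. Kcnn4 had 17.2 ± 0.492 TPM in forebrain and 64.6 ± 4.54 in cerebellum (log2 fold change 1.85, SE 0.07), Slc7a11 15.0 ± 0.478 and 36.7 ± 1.73 TPM (1.24, SE 0.07) and Tmem119 8.86 ± 0.445 and 18.9 ± 0.892 TPM (1.01, SE 0.11). Vsig4 (-2.90), F13a1 (-2.12), Igfbp3 (-2.42), Ppic (-2.00), Cav1 (-1.95) and the interferon-inducible Slfn4 (-2.03) were lower in cerebellum, and so was Folr2 (-1.72). Both regional contrasts called 184 genes higher and 317 lower in cerebellum, against 21.5 and 34.9 expected from independent lists, and 3 in opposite directions. Pearson's r of the regional log2 fold changes under the 2 ligands was 0.379 across 12419 genes, which are not independent replicates. The regional contrasts share no libraries. After removal of trends among transcripts of 1000 nt or more, r was 0.609, and 425 genes were called higher and 622 lower under both ligands, against 64.6 and 113 expected, with 9 in opposite directions.

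In this contrast 1675 genes passed, 654 higher and 1021 lower in cerebellum, and 3652 had an unadjusted p under 0.05. Of the calls, 1662 were without overlap between libraries, which their selection on the same libraries nearly fixes. The 10 highest named genes were again short, with mean transcript lengths of 586 nt or less: Atox1, Cox8a, Mt1, mt-Nd6, Wfdc17, Tceb2, Mif, Uqcrb, Rps15 and Hist2h2aa1 were listed at 0 in the 3 forebrain IL-34 libraries. Pagr1a (-3.96), Zfp600 (-3.25), Junos (-2.91) and Tbata (-2.57) completed the lowest named genes, Pagr1a, Zfp600 and Junos being uncertain as above. Of 41 type I interferon response genes 24 were lower in cerebellum and 2 higher, 29 and 2 when adjusted over the list alone, with Ifit2 at -0.88, Ifit3 at -0.54 and Ifit1 at -0.58 (adjusted p = 3.77e-11, and adjusted p = 0.161 with an estimated correlation). Of 50 G2/M genes 17 were lower and 1 higher, 20 and 1 when adjusted over the list alone (adjusted p = 1.73e-06, and 0.0322 with an estimated correlation). Border-associated macrophage genes were lower in 6 of 11 cases, 6 lower and 1 higher when adjusted over the list alone (adjusted p = 0.00157, and adjusted p = 0.0628 with an estimated correlation). Cholesterol biosynthesis genes were higher in 7 of 31 cases, 10 higher and 1 lower when adjusted over the list alone (adjusted p = 4.37e-05, and adjusted p = 0.17 with an estimated correlation). Of 26 genes of the ATF4 amino acid response 6 were higher, 9 when adjusted over the list alone, among them Slc7a11, Trib3 (0.44), Cars (0.29) and Nupr1 (0.71) (adjusted p = 6.86e-05, and adjusted p = 0.17 with an estimated correlation). After trend removal among longer transcripts Cars was at 0.07 and did not pass (adjusted p = 0.191), and Nupr1 turned to -0.84 (adjusted p = 0.00591). With the length floor as a covariate 126 genes passed. The count was 1029 and 838 without cerebellum IL-34 replicates 1 and 2, and 1077 and 1056 without forebrain IL-34 replicates 2 and 3.

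Markers of other brain cells moved in both directions between regions. The astrocyte list had 7 of 12 measured genes lower in cerebellum and 0 higher under each ligand, 9 when adjusted over the list alone (adjusted p = 5.04e-08 under CSF-1 and 2.95e-05 under IL-34, and 0.00554 and 0.0322 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, was at -1.3 under CSF-1 and -1.52 under IL-34, with 17.6 ± 1.92 TPM in forebrain and 6.54 ± 0.608 in cerebellum under CSF-1. Mlc1, Aldoc and Clu were the next by p, at -0.86, -0.84 and -0.95 under CSF-1. The contractile genes Acta2 (-1.20) and Tagln (-0.84) were lower among 6 genes of fibroblasts and mural cells, 3 when adjusted over the list alone (adjusted p = 0.0016, and adjusted p = 0.0789 with an estimated correlation). In the oligodendrocyte list 3 genes were higher in cerebellum under CSF-1 and 1 lower. The myelin gene Mbp was at 0.78 and Olig1 at -0.85, and the list as a whole did not pass there (adjusted p = 0.343). Mbp had 40.1 ± 3.51 TPM in forebrain and 69.7 ± 3.84 in cerebellum under CSF-1. Summed over their list, astrocyte markers held 936 and 950 TPM in forebrain with CSF-1 and IL-34 and 897 and 917 in cerebellum. This sum differed little between regions, so it does not follow the 7 genes called lower. In the means of the 4 groups, summed markers of the oligodendrocyte lineage held between 133 and 172 TPM. Those of fibroblasts and mural cells held between 19.4 and 38.8, and those of endothelial cells between 13.5 and 16.7. Markers of ependymal and choroid plexus cells, of which 4 passed the filter on low values, held 3.48 ± 0.734 and 4.50 ± 0.616 TPM in forebrain with CSF-1 and IL-34 and 23.4 ± 6.08 and 27.1 ± 15.7 in cerebellum. Most of the cerebellar sum was Ttr, with means of 18.4 and 22.6 TPM there and 0.0856 and 0.27 in forebrain. The ependymal marker Foxj1 went the other way and was lower in cerebellum (-0.57 under CSF-1 and -0.508 under IL-34). Markers of neurons, lymphocytes, and monocytes and neutrophils held at most 8.34, 4.43 and 1.81 TPM in the mean of any group.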

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

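The tests of transcript length and of trends, and the counts of splits with trends removed or with the mean ligand difference subtracted, were chosen after the results were seen; the other counts of splits were planned. The results here stand out because the ligand difference itself differed between regions in the interaction test, for 18 genes in all. Those named by the rule had adjusted p-values of 2.97e-08 (Atox1), 5.27e-05 (Cox8a, Mt1 and Mt2), 0.000235 (Tceb2), 0.00107 (Wfdc17), 0.0345 (Mrps5), 0.0186 (Focad), 0.0393 (Plekhm2) and 0.025 (Nup98).

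Of the 13 interaction genes with a mean transcript length under 1000 nt, 12 go with short transcripts that may be missing from libraries with a high length floor, as they were at 0 TPM in all 3 libraries with the highest floor and in all 9 outside cerebellum with IL-34, where the floor was lowest, but Gm6916, chosen after its values were seen, runs against this explanation (-3.51, SE 0.36), being lowest in cerebellum with IL-34. For the 5 measured with transcripts of 1000 nt or more, transcripts under 1000 nt of the same genes are a candidate explanation for part, since with the longer transcripts alone their median absolute log2 difference was 0.293 against 1.18 before, and 0 of 5 passed limma's test, with adjusted p-values of 0.0623 or more. Mrps5 went from 1.44 (SE 0.22) to -0.02 (SE 0.14) and Focad from 1.39 (SE 0.20) to -0.05 (SE 0.13), so their calls ended because the difference was gone, and Nup98 went from -0.58 (SE 0.09) to -0.29 (SE 0.08) and Plekhm2 from 0.81 (SE 0.13) to 0.57 (SE 0.16), but A230004M16Rik, chosen after its values were seen, was at -1.18 (SE 0.19) and then -1.22 (SE 0.18), which argues against this explanation for that gene, and its call ended only by the adjustment over genes. Whether trends of length and GC content account for what was left stays open, as 0 of the 5 passed before these were removed too, which took the median from 0.293 to 0.213. A regional difference in the response to IL-34 stays open as untested, because the lowest floors and the cerebellar IL-34 group are the same 3 libraries.

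Of 100 splits of the libraries within regions, 7 called as many genes as the real 18, the real one included, with 2438 in the highest other, and 82 called as many lists as the real 2, with 17 in the highest other. With transcripts of 1000 nt or more and trends removed, 12 of 100 splits had as many genes at an unadjusted p under 0.05 as the real 1377, and the highest other had 3540. These counts do not bear on chance, because a split that exchanges the ligands in 1 region turns the mean ligand difference into an interaction: the split that exchanges all forebrain libraries gave the 1667 genes, 17 lists and 3540 genes of the mean ligand contrast. The split with 2438 genes exchanges all 6 cerebellar libraries and forebrain replicate 1 of both ligands, so the structure that it points to includes the ligand difference, and why it called more than 1667 was not tested. With each gene's mean ligand difference subtracted, 1 of 100 splits, the real one, called 18 genes or more and the highest other called 2. This cannot exclude chance for the genes, because the subtracted difference was taken from the real groups. In genes at 0 in every forebrain library the subtraction itself puts a ligand difference into forebrain. Splits that mix the forebrain libraries then count it as spread, which lowers their calls. Chance is not excluded for the lists either, where 55 of 100 splits called 2 or more and the highest other 7. The 1377 genes with trends removed were reached by 5 of 100 splits, with 1521 in the highest other, so chance stays open there too.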

How the results depend on the processing

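Restricting to longer transcripts, removing trends, the length floor and the 9-library fit were chosen after seeing the data, as were leaving out each library for the list calls and the correlation of ligand effects, and quantile normalization and rescaling for the lists. The counts below are genes called by limma, in the order forebrain ligand (149), cerebellar ligand (1593), mean ligand (1667), interaction (18), region under CSF-1 (833) and region under IL-34 (1675), and those not given stayed within 1.5 times; the cause was not tested unless stated. Without the filter on low values, which tests more genes, the first 3 gave 87, 830 and 1106. Median-of-ratios scaling gave 253 for the first, and array weights gave 478 for the first and 2571 for the mean. With only the 6 libraries compared, and fewer degrees of freedom, the ligand contrasts gave 0 (1646 at an unadjusted p under 0.05) and 778 and the region under CSF-1 456. Transcripts of 1000 nt or more gave 734 for the first, 1 for the interaction, 1989 and 2598 for the regions. With trends removed as well, the first gave 880, the interaction 0 (1377 unadjusted) and the region under CSF-1 1805. A similar count did not mean the same genes. Of the main calls measured there, 703 of 1451 still passed in the same direction for the cerebellar ligand. For the mean ligand 1023 of 1579 did, and for the region under IL-34 1013 of 1511. The length floor as covariate gave 255, 37, 622 and 10 for the ligand contrasts and interaction and 126 for the region under IL-34. The 9 libraries gave 47, 689, 951, 8 and 340 for the first 5. Of 82 list calls over all contrasts, 10 held with an estimated correlation. In the opposite direction, 2 were called with longer transcripts, 3 with trends removed and 1 with the length floor: ribosomal proteins for the cerebellar ligand (in the first 2 settings) and the interaction (in the second), and respiratory chain genes for the region under IL-34 (in each).

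With the replicate number as a replicate block the forebrain ligand count was 83 and the cerebellar one 986; a culture replicate block within region gave 0 (1295 unadjusted), 194, 395 and 8 for the ligand contrasts and interaction. Same-numbered libraries of the ligands did not deviate together (correlations across genes of -0.4, 0.13 and -0.42 in forebrain and -0.079, -0.013 and -0.081 in cerebellum), so the numbers were not taken as pairs.

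Leaving out each library in turn gave 29 to 163, 299 to 1769, 925 to 2081, 12 to 132, 413 to 918 and 838 to 1772 genes in the order above, 81 to 86 list calls, and -0.212 to 0.156 for the correlation of ligand effects across genes. A group left with 2 libraries is assumed to vary like the others.

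Of 2936 values of the 110 pairs of gene and contrast named by size of change under alternatives, 2698 kept direction and call, 234 kept direction and lost the call, and 4 turned direction. These were Cox16 in the mean ligand contrast, -0.98 with longer transcripts and -0.97 with trends removed, and the interaction of Mrps5 (-0.016) and Focad (-0.051) with longer transcripts. Named genes past the threshold in all 12 fits without a library numbered 7 of 20 in forebrain, 16 of 20 in cerebellum, 20 of 20 in the mean and in each regional contrast, and 6 of 10 in the interaction. Depth is unknown, so what it limits cannot be stated.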

Other observations

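The tests of length and GC trends, of ligand dose and of the cell types in the regional pattern were chosen after the results were seen; the count of cell cycle genes and the splits were planned. Genes for lipid handling under LXR moved with the ligand in both directions: of 23 measured, 5 rose and 2 fell with IL-34 in the mean of both regions, 6 and 2 when adjusted over the list alone. Median-of-ratios scaling gave 9 higher and 1 lower. Ch25h (-0.91) fell while Fabp5 (0.73), Fabp4 (0.99) and Soat1 (0.26), which esterifies cholesterol, rose (camera adjusted p = 0.000861, and adjusted p = 0.0656 with an estimated correlation). After trend removal among transcripts of 1000 nt or more Fabp5 was at 0.38 and did not pass (adjusted p = 0.0587), and Fabp4 was at 0.53. Antigen presentation genes rose in 2 of 12 cases for MHC class II, 3 when adjusted over the list alone, namely Ctss (0.27) and Cd74 (0.23), the invariant chain (adjusted p = 0.00247, and adjusted p = 0.0656 with an estimated correlation). For MHC class I, 3 of 20 rose and 1 fell, 5 and 1 when adjusted over the list alone, with H2-D1 at 0.15, Psmb9 at 0.27, Psmb8 at 0.17 and Calr at -0.25 (adjusted p = 0.000187, and adjusted p = 0.288 with an estimated correlation). With median-of-ratios scaling 6 were higher. Psmb8 was at 0.09 with trends removed and did not pass (adjusted p = 0.282).

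Between regions, genes of the ATF4 response to amino acid shortage were higher in cerebellum under CSF-1 in 4 of 26 cases and lower in 0, 8 and 0 when adjusted over the list alone. They were Slc7a11 (1.31), the pseudokinase gene Trib3 (0.52), Phgdh (0.46), which opens serine synthesis, and Chac1 (0.47) (adjusted p = 0.000432, and adjusted p = 0.249 with an estimated correlation). Under IL-34, glycolysis genes were lower in cerebellum in 9 of 23 cases, 12 lower and 1 higher when adjusted over the list alone, with Aldoc (-1.29), which astrocytes also make, the lactate exporter gene Slc16a3 (-0.53), Ldha (-0.36) and Pgk1 (-0.60) having the smallest p (adjusted p = 0.000676, and adjusted p = 0.386 with an estimated correlation). Pgk1 was at -0.25 with trends removed and did not pass (adjusted p = 0.0689). The lysozyme gene Lyz2 had 40700 and 43900 TPM in the forebrain groups with CSF-1 and IL-34 and 28400 and 28000 in the cerebellar groups (log2 fold change -0.52 and -0.65, adjusted p = 3.25e-05 and 3.5e-06). Dab2 and Ms4a7, abundant members of the border-associated macrophage list chosen after their values were seen, did not pass between regions (Dab2 0.13 and 0.13, Ms4a7 0.08 and 0.16 under CSF-1 and IL-34). With trends removed Ms4a7 passed as higher in cerebellum under both ligands (0.18 and 0.16, adjusted p = 0.022 and 0.0324), and Dab2 under IL-34 (0.17, adjusted p = 0.0105).

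The genes called for the ligand in forebrain, most with the same sign in cerebellum, may be a response to which ligand was present. Trends of transcript length and GC content do not account for them as a whole, since 138 of the 146 that can be measured with transcripts of 1000 nt or more still passed in the same direction after these were removed. This covers the forebrain calls only. Of the cerebellar ligand calls measured in the same way 703 of 1451 still passed, so such trends stay open as a cause of many of those. Of the 80 genes lower in both regions, 5 are in the cell cycle lists. This count cannot decide whether fewer cycling cells were the whole cause. In forebrain only 4 G1/S genes and 1 G2/M gene were called lower, so no more list members could be among the 80. Ligand and dose cannot be told apart, because 0 of the 2 ligands were given at more than 1 dose and no dose was shared. A difference in the response to the ligands themselves stays open as a hypothesis, untested against dose.

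Genes lower in cerebellar than in forebrain cultures under both ligands, Folr2 and F13a1 among them, may mark a regional state of microglia or a different mix of cells. Length and GC trends do not account for the pattern as a whole: 272 of the 306 that can be measured with longer transcripts still passed under both ligands after trend removal. A lower share of microglia in the forebrain cultures would make the markers of the other cell types that pass all lower in cerebellum, and of 38 such markers 12 were lower there and 4 higher under both ligands (Mbp, Mobp and Ttr among them). Fewer border-associated macrophages in the cerebellar cultures cannot be told apart from a change within microglia, as 6 of 11 members were lower under CSF-1 and cultured microglia may make the rest. The region of origin, which the design names, stays among the open explanations.

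For the mean ligand difference chance can be excluded: 1 of 100 splits within regions, the real one, called 1667 genes or more, and the highest other called 130. For its lists 1 of 100 splits reached the real 17, with 16 in the highest other. The median other split called 5 lists, and 93 other splits called at least 1. List calls at the preset correlation were thus common in splits other than the real one. The other contrasts compare 3 with 3 libraries, and their 10 splits are too few for a share under 0.05. The real and the highest other counts of genes there were 149 and 2 in forebrain, 1593 and 2 in cerebellum, 833 and 28 for the region under CSF-1, and 1675 and 1 for the region under IL-34. For lists they were 16 and 11, 15 and 6, 17 and 15, and 15 and 10 in that order. The median other split called 5, 4, 6 and 4 lists in the same order.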
